A study of Homo sapiens with 8 samples.

How the data were processed

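RNA from BJ cells, a line of human skin fibroblasts, was sequenced in 8 libraries that the labels place in 4 groups of 2. The cell line is that of the labels; the design text of the series names a mouse mesenchymal line and knockdowns that no label holds, and it was not used. The long noncoding RNA PURPL was overexpressed (group OE-PURPL, with PCDNA as its control) or knocked down with an ASO, an antisense oligonucleotide (group ASO-PURPL, with ASO-NC as its control). Libraries were made from total RNA with an mRNA library kit, per the labels' protocols. STAR and Cufflinks, without versions, and the human build hg38 are named per the submitters' processing notes, and the gene annotation is not given in the sources used here.

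The deposited values are FPKM (fragments scaled by transcript length and by the size of the library). This unit was inferred, since no column names it: the authors' processing notes name Cufflinks, the values are not whole numbers, and the library sums ran from 464110 to 587727 and so are not those of TPM or CPM. The authors deposited 3 tables. For replicate 1, the overexpression pair and the knockdown pair stand in separate tables, in which no value lies below 0.01 FPKM, and each of these tables also holds a column of log2 fold changes by the authors. That deposited log2 column equals the log2 ratio of FPKM plus 1 to within 0.0015 in each row. Replicate 2 of all 4 groups stands in the third table, where zeros were kept. Read numbers are unknown for all 8 libraries, so no counting error could be attached to a level, and FPKM from Cufflinks are model estimates rather than read counts. Genes with near-identical copies, such as pseudogenes, small nuclear RNAs and duplicated segments, and genes that overlap each other are uncertain for that reason. Among the genes named, this holds for the pseudogenes, the copies of U1 RNA, POLR2J2, HSPA1B, AKR1C1 and the related chemokines CXCL1 and CXCL2, and for the antisense gene FARP1-AS1, since use of strand is not given in the sources used here.

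Each table held 60635 rows. Of 1264 rows that repeated a gene name, the row with the highest mean was kept, chosen in each table separately. A repeated name can therefore rest on different rows in different tables. In addition 1 gene with a cell that was not a number in the PCDNA replicate 1 column was left out, which left 59370 genes. Names were matched to GENCODE release 29 (the same assembly as hg38) for coordinates, transcript length and GC content, and 37747 names were found there. Because the tables may have been normalized separately, treated libraries were compared only with the control of the same table and replicate number. For each gene the log2 ratio of FPKM plus a pseudocount of 1 was taken in each of the 4 pairs, so that fold changes of genes with low levels are understated. Genes with a mean of at least 1 FPKM over the 4 libraries of either comparison were tested, which gave 14977 genes.

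The 4 ratios per gene were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean level), with a coefficient for overexpression and a coefficient for knockdown that share an estimate of the spread. Residual degrees of freedom were 2 per gene, and the fit added 3.34 from the other genes. The difference and the sum of the 2 coefficients were tested as well, and genes past these tests were counted where the 2 changes had opposite signs (difference) or equal signs (sum), so a single comparison can carry either. Adjusted p-values are from Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The replicate block follows the deposited tables. Across genes, the deviations of treated and control libraries with the same number correlated with r = 0.14 in the overexpression groups and r = 0.49 in the knockdown groups.

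Before the data were examined, 35 gene lists, the design, 20 core genes and the rule for naming genes were fixed. List members were compared with all other tested genes by camera in its pre-ranked form, on z-scores of the moderated statistics, with a preset correlation of 0.01 and adjustment over 66 tests (33 lists in 2 comparisons). The planned camera call on the ratios themselves was replaced by this form so that lists and genes rest on the same fit. Genes, not libraries, are the units of this form, so its p-values do not measure the spread of a list between libraries. Camera with a correlation estimated per list and fry, which works on the ratios themselves, were alternatives. The estimate rests on 2 residual degrees of freedom, and values below 0 were set to 0. It was 0 for cholesterol biosynthesis and TGF-beta targets and -0.04 for histones, below the preset value and so less strict. With an estimated correlation, 4 of the 12 calls for overexpression and 1 of the 7 for knockdown held, and fry called 0 lists (lowest adjusted p 0.222). The endothelial list (3 of 12 members tested) and the melanocyte list (4 of 12) fell under the minimum of 5 members. Some lists share members, such as JUNB, ATF3, IER3, IL6 and CXCL8, so their calls are not independent. Named genes are PURPL, the core genes, up to 10 genes in each direction that passed the test in both pairs, filled to 10 by the size of the smaller absolute ratio of the 2 pairs where fewer passed, and up to 4 members of a list by that same measure. Genes called only by AC, AL or LOC clone names were skipped. List members that passed when adjusted over the list alone are named as well. Some genes that this rule takes are not reported here.

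The fit was tested on simulated ratios for the 14977 genes. These were drawn as independent normal values with spreads from the fitted prior. They hold no correlation between genes and no genes that jump between near 0 and high FPKM, so false calls from either source were not tested. Of 50 genes changed by 0.5, 1, 2 and 4 on the log2 scale in the overexpression ratios, 0, 15, 44 and 49 were recovered at each size, with 2 false calls. In 50 simulated sets without any change, 0 gave a call in the overexpression comparison. A list of 50 genes shifted by -0.2 in the simulated knockdown ratios was called and an unshifted list was not.

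Alternatives were other pseudocounts (0.1 and 5), no filter or a filter at 5 FPKM, a rescaling by a trimmed mean (30% of log ratios and 5% of levels trimmed on each side), median centring, eBayes without a trend, each comparison alone, group means without the replicate block after quantile normalization, genes above the median level, and each pair left out. Where a pair was left out, the remaining pair of that comparison was taken to vary like the pairs of the other comparison. The other comparison then rested on its own pairs, so its genes had the same fit as in that comparison alone. Removal of a smooth trend on transcript length and GC content (loess span 0.5) and a test of protein-coding genes alone were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.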

Results

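Gene expression was measured by RNA sequencing in BJ cells, a line of human skin fibroblasts, after the long noncoding RNA PURPL was raised or lowered. The series concerns noncoding RNAs in the aging of fibroblasts, and the 2 comparisons ask which genes follow PURPL. Each of the 4 groups (OE-PURPL and its control PCDNA, ASO-PURPL and its control ASO-NC) held 2 libraries. Between 13464 and 14623 genes per library reached 1 FPKM, and the 10 highest held 6.25% to 9.26% of the summed FPKM. Sequencing depth was unknown.

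The overexpression and the knockdown libraries differed in their baseline. Interferon-stimulated genes, such as ISG15, IFIT1 and MX1 (named after their values were seen), had a median of 142 and 134 FPKM in the PCDNA libraries and of 9.05 and 9.93 FPKM in the ASO-NC libraries. All 50 measured members were higher in PCDNA in both replicates, with a median log2 difference of 3.90 inside the table that held both arms and of 3.78 across the separately deposited tables of replicate 1. Genes of G2/M and mitosis had medians of 7.46 and 7.56 FPKM in PCDNA against 1.88 and 1.84 FPKM in ASO-NC, and 56 of 57 members were higher in both replicates. NF-kB targets were higher by a median of 0.87 and 1.16 on the log2 scale, with IL6 at 169 and 155 FPKM against 11.1 and 9.66 FPKM. Core genes differed as well. Mean FPKM in PCDNA and ASO-NC was 404 and 674 for CDKN1A, 3.5 and 10.7 for CDKN2B, and 5.42 and 1.22 for LMNB1. For PURPL it was 5.58 and 13. No test was run between the arms. Where overexpression is compared with knockdown, this baseline cannot be told apart from the perturbation.

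PURPL itself (chromosome 5, 27472292 to 27496401 on the plus strand, a long intergenic noncoding RNA gene) followed the labels in every pair. It stood at 153 and 238 FPKM in the OE-PURPL libraries against 5.42 and 5.73 FPKM in PCDNA, which is 28.3-fold and 41.6-fold higher. On the log2 scale PURPL rose by 4.87 (SE 0.16, adjusted p = 0.00511, limma). In the ASO-PURPL libraries it stood at 6.31 and 4.24 FPKM against 16.2 and 9.74 FPKM in ASO-NC, 61.0% and 56.4% lower. The knockdown estimate was -1.13 (SE 0.16), which did not pass the test over all genes (adjusted p = 0.374). The authors' deposited table gave log2 fold changes of 4.587 and -1.233 for replicate 1. Leaving out the OE-PURPL and PCDNA pair of replicate 1 or 2 gave adjusted p-values of 0.0696 and 0.093 for the overexpression, and leaving out either knockdown pair gave 0.365.

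**Figure D1:**
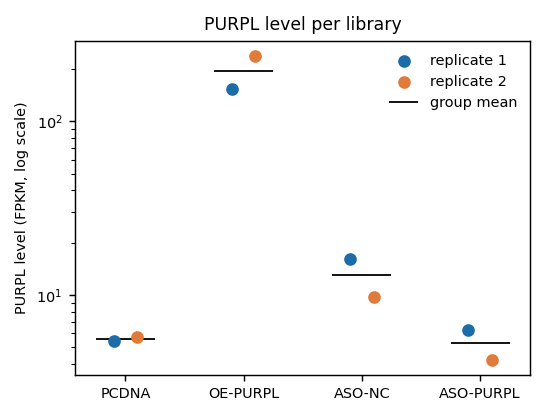
PURPL level in FPKM on a log axis for each of the 8 libraries, with points for the replicates and a line for the mean of each group. The OE-PURPL libraries stood at 153 and 238 FPKM and the ASO-PURPL libraries at 6.31 and 4.24 FPKM, below both ASO-NC libraries (16.2 and 9.74 FPKM).

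Apart from PURPL, overexpression changed 3 single genes past the threshold, and most of its calls were of groups of genes. Immediate early genes rose together and genes of mitosis fell together, each by a modest amount, in both pairs. These are calls of camera, and fry called neither list (adjusted p = 0.297 and 0.323). Genes of oxidative phosphorylation, ribosomal proteins and several stress and secretory lists were also higher as groups, calls that did not hold with an estimated correlation. Neither the p53 target list nor the list of senescence regulators passed camera, which tests for a shift in a shared direction.

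In total 4 genes rose and 0 fell among 14977 tested (limma, adjusted p under 0.05), while 2061 genes had an unadjusted p under 0.05 against 749 expected by chance. Besides PURPL these were CTB-79E8.3 (28.4 and 24.7 FPKM, adjusted p = 0.0064), RP11-193F5.1 (20 and 18.7 FPKM, adjusted p = 0.0064) and CH17-13I23.3 (24 and 12.5 FPKM, adjusted p = 0.0436), all listed at 0.01 and 0 FPKM in the PCDNA libraries. Replicates of the same group, which stand in different tables, differed by a mean of 33.2 genes that stood at most at 0.01 FPKM in one library and at 10 FPKM or more in the other. These names were not matched to GENCODE 29, so no coordinates are given. The ratios of both pairs followed transcript length and GC content across genes. The 2061 genes therefore cannot be read as a count of genes that follow PURPL. Log2 ratios of at least 1 in both pairs were seen for 21 genes upward and 14 downward. The next by size, none of which passed the test, were RP11-809N8.5 (292 and 100 FPKM, listed at 0.01 and 0 in PCDNA), RP11-90D4.5, RN7SL181P, RPS28P4, PTMAP4 and LLNLR-284B4.1 upward, most of them clone-named genes or pseudogenes. Downward they were TMSB4XP2, TMEM135, CKS1BP2, RP11-373D23.2, IMMP2L, TMEM164, POLR2J2, RP11-417L19.6, RP11-56B16.4 and RP11-298I3.5. TMEM135 (chromosome 11, 87037844 to 87323758) stood at 5.11 and 6.44 FPKM after overexpression against 19.6 and 43.4 FPKM in PCDNA (adjusted p = 0.206). With a pseudocount of 0.1, 3 genes passed and RP11-193F5.1 did not (adjusted p = 0.179), and with a pseudocount of 5, 2 genes passed and CTB-79E8.3 and CH17-13I23.3 did not (adjusted p = 0.111 and 0.245). RP11-193F5.1 also missed the threshold with a filter at 5 FPKM (adjusted p = 0.0564), and CH17-13I23.3 in eBayes without a trend (adjusted p = 0.129). Without a filter or in the fit of the overexpression pairs alone 0 genes passed. With any pair left out, none of the 4 genes kept its call, and any gene that passed was another.

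Immediate early genes, the transcription factors and regulators that cells induce within minutes of a stimulus, rose as a group (median log2 change 0.23, 28 members, camera adjusted p = 9.53e-06). The call held with an estimated correlation (adjusted p = 0.0136). Of the 28 members, 21 were higher in both pairs and 3 lower. Over all genes 0 members passed, and adjusted over the list alone 10 rose: JUNB (0.72, SE 0.10), FOSB (0.85, SE 0.20), IER2 (0.59, SE 0.10), IER3 (0.57, SE 0.13), FOS (0.57, SE 0.16), JUND (0.67 and 0.26 in the pairs), IER5, EGR1, FOSL1 and ATF3. JUNB, FOS, FOSB, FOSL1 and JUND encode subunits of the AP-1 transcription factor. JUNB stood at 189 and 170 FPKM after overexpression against 108 and 109 FPKM in PCDNA.

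Genes of G2/M and mitosis fell as a group (median -0.19, 57 members, adjusted p = 3.04e-05, and adjusted p = 0.0141 with an estimated correlation). In both pairs 39 members were lower and 3 higher, with 0 past the test, whether adjusted over all genes or adjusted over the list alone. The members with the largest paired ratios were HMMR, a spindle-associated receptor (-0.67 and -0.62), ANLN, a scaffold of cytokinesis (-0.50 and -0.63), MKI67, the proliferation marker (-0.44 and -0.59), and KIF11, a spindle motor (-0.48 and -0.35). Genes of G1/S and DNA replication did not move with them (median 0.04, 46 members, adjusted p = 0.561).

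Nuclear-encoded genes of oxidative phosphorylation were higher as a group (median 0.24, 0.12 and 0.31 in the pairs, 70 members, adjusted p = 2.22e-10), with 50 members higher and 1 lower in both pairs. ATP5ME, ATP5MC1, COX5B and COX6A1 had mean log2 changes of 0.40 to 0.48. Cytosolic ribosomal proteins were higher too (median 0.18, 0.09 and 0.28 in the pairs, 77 members, adjusted p = 1.27e-07), with 50 higher and 0 lower in both pairs, among them RPS2, RPL8, RPLP2 and RPS15 (0.40 to 0.43). Neither call held with an estimated correlation (adjusted p = 0.385 and adjusted p = 0.66 in that order). The mitochondrially encoded genes did not pass (median 0.01, 15 members, adjusted p = 0.911).

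Inflammatory and secretory genes followed. NF-kB targets rose as a group (median 0.20, 0.13 and 0.25 in the pairs, 29 members, adjusted p = 0.00325, adjusted p = 0.342 with an estimated correlation), 17 being higher and 3 lower in both pairs. CXCL2 had ratios of 0.61 and 1.15 and IL6 of 0.34 and 0.94. Senescence-associated secretory factors rose as a group (median 0.15, 0.10 and 0.25 in the pairs, 45 members, adjusted p = 0.0139, adjusted p = 0.643 with an estimated correlation). This list shares IL6, CXCL8, CXCL1, CXCL2 and other members with the NF-kB list, so these calls are not independent. Adjusted over the list alone, IGFBP6 (0.51, SE 0.09) and PLAUR (0.48, SE 0.09) rose and NRG1, a ligand of the ERBB receptors, fell by 0.55 (SE 0.09). IGFBP6, which binds insulin-like growth factors, stood at 1130 and 1210 FPKM against 805 and 841 FPKM. Interferon-stimulated genes did not pass (median 0.12, 50 members, adjusted p = 0.273).

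The ATF4 list of the integrated stress response passed (median 0.11, 36 members, adjusted p = 0.0289, adjusted p = 0.384 with an estimated correlation). Adjusted over the list alone, 6 members rose, namely NUPR1 (0.68, SE 0.11), PPP1R15A (0.63, SE 0.10), DDIT3 (0.46, SE 0.10), CEBPB, SLC3A2 and CHAC1, while the amino acid transporter SLC38A2 fell by 0.38 (SE 0.09). NRF2 and antioxidant genes passed (median 0.20, 33 members, adjusted p = 0.00745, adjusted p = 0.204 with an estimated correlation), with HMOX1, the heme-degrading oxygenase, at 0.44 and 0.71. Lysosome and autophagy genes passed (median 0.17, 0.07 and 0.22 in the pairs, 43 members, adjusted p = 0.00156, adjusted p = 0.384 with an estimated correlation), as did glycolysis and hypoxia genes (median 0.11, 33 members, adjusted p = 0.0298, adjusted p = 0.312 with an estimated correlation). Replication-dependent histones (median 0.23, 0.20 and 0.13 in the pairs, 12 members, adjusted p = 0.0222) and TGF-beta targets (median 0.16, 0.10 and 0.14 in the pairs, 29 members, adjusted p = 0.036) were higher as groups. The histone list holds 46 names, older and newer symbols of the same genes among them, of which 15 were found in the data. Both calls held with an estimated correlation (adjusted p = 0.0441 and adjusted p = 0.0494), the estimates being -0.04 and 0. Within the TGF-beta list JUNB rose when adjusted over the list alone, and GADD45B (0.59, SE 0.08) did so in the YAP/TEAD list, which itself did not pass (median -0.03, adjusted p = 0.911).

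Of the 12 lists called after overexpression, immediate early genes, mitosis and oxidative phosphorylation passed with any pair left out. Without OE-PURPL and PCDNA replicate 2, the calls of NF-kB targets (adjusted p = 0.0971), ribosomal proteins (0.106), the ATF4 list (0.151), lysosome (0.187) and secretory factors (0.299) ended, and without replicate 1 those of NRF2 genes (0.0786), histones (0.129), TGF-beta targets (0.24) and glycolysis (0.345). The TGF-beta call also ended without either knockdown pair (0.0685 and 0.0613), and without the replicate block and with quantile normalization the calls of mitosis (0.000271) and immediate early genes (0.000232) were kept while the other 10 ended, oxidative phosphorylation at an adjusted p of 0.0619. Without the block and with quantile normalization, the medians of those 10 lists ran from 0.01 (TGF-beta targets) to 0.17 (histones), with ribosomal proteins at 0.02. A filter at 5 FPKM ended the calls of TGF-beta targets (0.118), secretory factors, the ATF4 list and glycolysis (0.0851 each), and eBayes without a trend those of TGF-beta targets (0.0564), the ATF4 list and glycolysis (0.055 each). The log2 ratios correlated across genes with transcript length (Spearman -0.34 and -0.36) and GC content (0.46 and 0.37), and with this trend removed the list medians were 0.17 for oxidative phosphorylation, 0.12 for ribosomal proteins, -0.16 for mitosis and 0.13 for immediate early genes. With that trend removed, TGF-beta targets (adjusted p = 0.0615) and the ATF4 list (0.0963) no longer passed. With that trend removed and an estimated correlation, the call of immediate early genes held (adjusted p = 0.000181) and that of mitosis ended (adjusted p = 0.127). The estimate for immediate early genes was then -0.04, taken as 0.

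Among senescence genes, CDKN2A and CDKN2B, neighbouring inhibitors of the cyclin-dependent kinases that drive entry into the cell cycle, had overexpression ratios of 0.76 and 0.41 and of 0.37 and 0.51. Neither passed over all genes (adjusted p = 0.324 and 0.325). CDKN1A, another cyclin-dependent kinase inhibitor, had ratios of 0.26 and 0.11, and MDM2, a ubiquitin ligase, of -0.26 and -0.83. LMNB1 had -0.17 and -0.32, GDF15 0.36 and -0.09, HMGB1 0.03 and 0.12, CCND1 0.02 and -0.16, CXCL8 0.09 and 0.68, and IGFBP3 -0.02 and 0.23. The p53 list had a median of -0.06 (39 members, adjusted p = 0.273), with ZMAT3 (-0.40 and -0.39) and TP53INP1 (-0.32 and -0.51) among its largest paired ratios. The senescence regulators had a median of 0 (28 members, adjusted p = 0.966). The list of PURPL partners, which holds MYBBP1A and ELAVL1 among others, had a median of -0.08 (7 members, adjusted p = 0.561). The reference genes GAPDH and ACTB had overexpression ratios of 0.26 and 0.28 and of 0.05 and -0.18. Collagens (median 0.08, 36 members, adjusted p = 0.402) did not pass, with COL1A1 at -0.08 and -0.38 and ACTA2 at -0.14 and 0.07.

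The remaining lists did not pass after overexpression. Their medians were -0.01 for other matrix genes (adjusted p = 0.936), 0.06 for matrix proteases (0.611), -0.04 for contractile genes (0.824), 0.06 for heat shock (0.503) and 0.05 for the unfolded protein response (0.764). They were 0.05 for cholesterol biosynthesis (0.224), in which MVD and PMVK of the mevalonate pathway rose when adjusted over the list alone (0.59 and 0.50, SE 0.10), -0.05 for fatty acid genes (0.911), 0.01 for ribosome biogenesis (0.89), -0.09 for DNA repair (0.143) and -0.01 for ERK feedback (0.409). Fibroblast markers had -0.02 (0.904), keratinocyte markers 0.19 (0.162) and immune cell markers 0.14 (0.292).

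**Figure D2:**
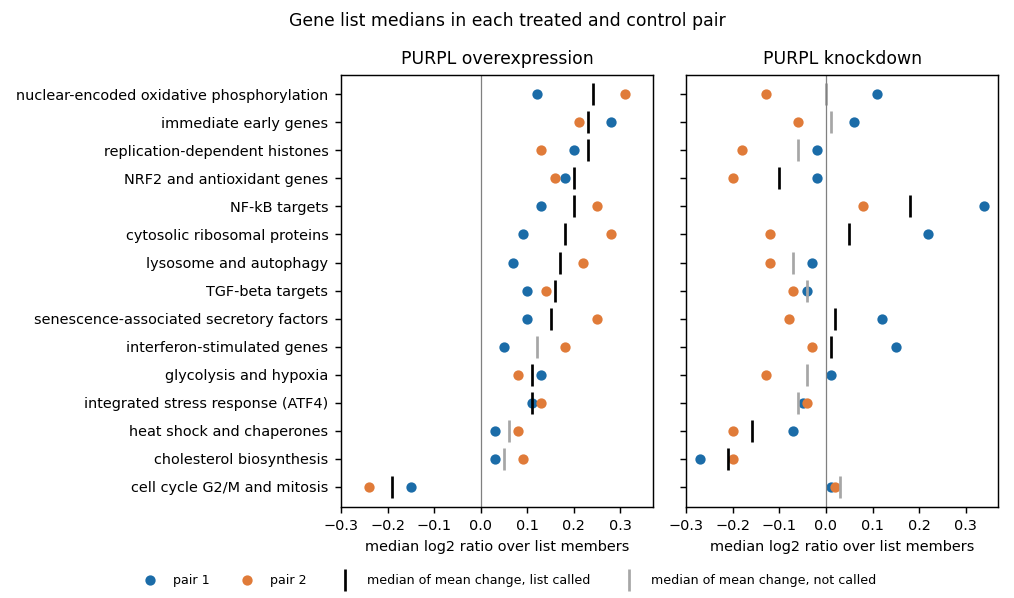
Median log2 ratio over the members of each gene list called in either comparison, per pair (points) and for the mean change (vertical lines, black where the list passed the test and grey where it did not). Immediate early genes lay above 0 and mitotic genes below 0 in both overexpression pairs, and cholesterol biosynthesis lay below 0 in both knockdown pairs (-0.27 and -0.20).

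After knockdown of PURPL the genes of cholesterol biosynthesis were lower as a group, the knockdown call that held with an estimated correlation. That estimate was 0 for this list, below the preset 0.01, and fry did not call the list (adjusted p = 0.256). DHCR7, which makes cholesterol in the last step of the pathway, stood at 80.7 and 83.1 FPKM against 109 and 103 FPKM in ASO-NC. NF-kB targets rose as a group and heat shock genes fell as a group, calls that did not hold with an estimated correlation. No single gene passed the test over all genes.

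By limma 0 of 14977 genes passed at an adjusted p under 0.05, and 1225 had an unadjusted p under 0.05 against 749 expected by chance. Without the replicate block and with quantile normalization 1 gene passed, as did 1 with a pseudocount of 0.1. In both pairs 32 genes were higher and 34 lower by at least 1 on the log2 scale. The largest upward were copies of the U1 small nuclear RNA (RNU1-2, RNU1-27P, RNVU1-29, RNU1-1, RNU1-28P and RNVU1-18), near-identical copies whose values are uncertain, then FARP1-AS1, RP11-373D23.2, RN7SKP16 and 1 more clone-named gene. Downward they were TMSB4XP2, RP11-134F2.7, CH17-13I23.3, RP11-351I24.3, MTCO2P2, TXNP6, RP11-56G10.2, IMMP2L, RP11-3P17.5 and RP11-234N17.1. None of these passed (lowest adjusted p = 0.191).

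The cholesterol biosynthesis list fell (median -0.21, 25 members, camera adjusted p = 1.49e-07, and adjusted p = 7.26e-09 with an estimated correlation). In both pairs 21 members were lower and 1 higher. DHCR7 had ratios of -0.43 and -0.30 and INSIG1, a sterol-regulated protein of the endoplasmic reticulum, -0.33 and -0.35. HSD17B7 went the other way (0.55 and 0.32). Over all genes, and adjusted over the list alone, 0 members passed. Fatty acid and lipid droplet genes did not pass (median -0.10, 21 members, adjusted p = 0.0941).

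NF-kB targets rose as a group (median 0.18, 29 members, adjusted p = 0.000422, adjusted p = 0.287 with an estimated correlation), more in pair 1 (median 0.34) than in pair 2 (0.08). CXCL1 rose when adjusted over the list alone (0.63, SE 0.10). CXCL2 (1.22 and 0.47), CXCL8 (0.68 and 0.47) and PTX3 (0.75 and 0.39) had the next largest paired ratios. Secretory factors (median 0.02, 45 members, adjusted p = 0.0289) and interferon-stimulated genes (median 0.01, 50 members, adjusted p = 0.0298) were called upward with pair medians of opposite sign, and neither held with an estimated correlation (adjusted p = 0.652 and adjusted p = 0.646). IL1A had ratios of 0.98 and 0.58 and CXCL11 of 0.67 and 0.55, while USP18 had -0.31 and -0.33. CXCL11 stood near the pseudocount, at means of 0.797 FPKM in ASO-NC and 1.77 FPKM in ASO-PURPL.

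Heat shock genes and chaperones fell as a group (median -0.16, -0.07 and -0.20 in the pairs, 21 members, adjusted p = 0.0021, adjusted p = 0.204 with an estimated correlation). In both pairs 12 members were lower and 0 higher, among them HSPA1B, HSPB8, BAG3 and HSPH1 (-0.35 to -0.23). NRF2 and antioxidant genes fell as a group (median -0.10, -0.02 and -0.20 in the pairs, 33 members, adjusted p = 0.036, adjusted p = 0.323 with an estimated correlation), with GCLC, GSR, GPX3 and AKR1C1 between -0.40 and -0.32. Ribosomal proteins were called upward (median 0.05, 77 members, adjusted p = 0.00745, adjusted p = 0.846 with an estimated correlation), although pair 1 had a median of 0.22 and pair 2 of -0.12, and the call turned downward without ASO-PURPL and ASO-NC replicate 1 (adjusted p = 0.0224). Without that pair the calls of NF-kB targets (adjusted p = 0.129), secretory factors (0.755) and interferon-stimulated genes (0.912) ended, and without replicate 2 those of heat shock (0.201) and NRF2 genes (0.638). The NRF2 call also ended without either overexpression pair (0.0694 in both cases), and without the replicate block and with quantile normalization the calls of NF-kB targets and cholesterol biosynthesis (0.000232 each) were kept while the other 5 ended. NRF2 genes also did not pass with a filter at 5 FPKM, trimmed-mean scaling, median centring, eBayes without a trend, the knockdown alone or protein-coding genes alone (adjusted p from 0.057 to 0.0773). Without a filter the calls of ribosomal proteins (0.0642), interferon-stimulated genes (0.133) and secretory factors (0.173) ended, and those of the latter 2 ended in eBayes without a trend as well (0.0697 and 0.0564).

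Of p53 targets, BBC3, which encodes the proapoptotic protein PUMA, rose when adjusted over the list alone (0.67, SE 0.11), at 29.7 and 20.9 FPKM against 18.3 and 12.8 FPKM. LIF, AEN and GADD45A had mean changes of 0.49, 0.37 and 0.27, and the list as a whole did not pass (median -0.01, mean 0.03, 39 members, adjusted p = 0.213). Core genes had knockdown ratios of 0.08 and -0.11 for CDKN1A, -0.26 and -0.52 for CDKN2A, -0.47 and -0.43 for CDKN2B, 0.25 and 0.10 for MDM2, 0.38 and 0.26 for LMNB1, and -0.37 and -0.23 for COL1A1. LMNB1 stood near the pseudocount, at means of 1.22 FPKM in ASO-NC and 1.76 FPKM in ASO-PURPL. GAPDH had 0.13 and -0.14 and ACTB 0.17 and -0.13. CDKN1C had -1.39 and -0.59 (adjusted p = 0.582). The senescence regulators did not pass (median -0.03, adjusted p = 0.837), nor did collagens (median -0.09, adjusted p = 0.0568). In the immediate early list, which did not pass (median 0.01, mean -0.08, adjusted p = 0.911), ARC fell by 1.33 (SE 0.16) when adjusted over the list alone, from 6.32 and 5.93 FPKM to 1.65 and 2.02 FPKM.

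The remaining lists did not pass after knockdown. Their medians were 0.02 for PURPL partners (adjusted p = 0.904), -0.04 for G1/S (0.698), 0.03 for G2/M and mitosis (0.1), -0.05 for other matrix genes (0.698), -0.05 for matrix proteases (0.858), -0.04 for TGF-beta targets (0.911) and -0.07 for contractile genes (0.595). They were 0.03 for YAP/TEAD targets (0.422), -0.08 for the unfolded protein response (0.143), -0.06 for the ATF4 list (0.911), -0.04 for glycolysis (0.492), 0 for oxidative phosphorylation (0.698), 0.06 for mitochondrially encoded genes (0.363), -0.07 for lysosome (0.163) and -0.04 for ribosome biogenesis (0.698). DNA repair had 0.04 (0.554), histones -0.06 (0.746), ERK feedback -0.10 (0.492), fibroblast markers -0.05 (0.345), keratinocyte markers -0.02 (0.911) and immune cell markers 0.05 (0.189). Camera ranks a list against the other genes. After knockdown its direction differed from the sign of the median for G1/S, PURPL partners, keratinocyte markers and p53 targets, and from the sign of the mean for immediate early genes and oxidative phosphorylation, and after overexpression from the mean of the senescence regulators. None of these lists passed in the comparison concerned.

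**Figure D3:**
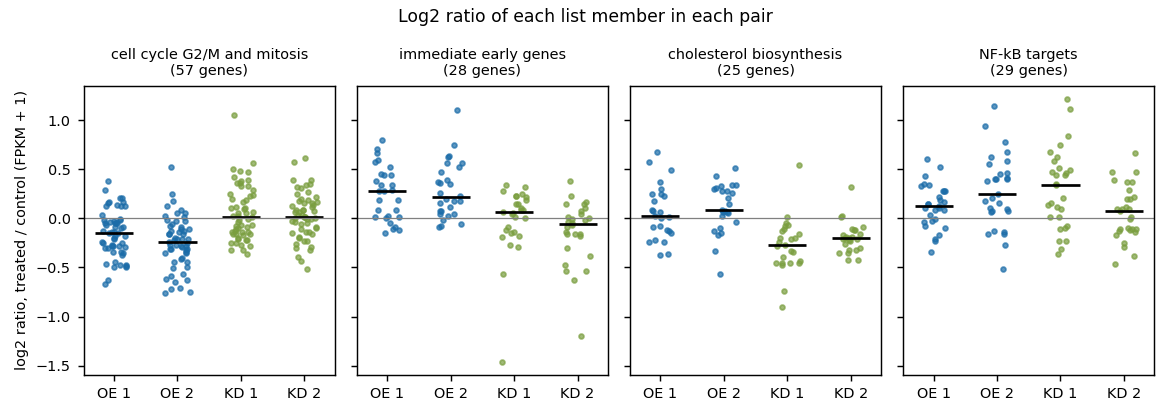
Log2 ratio of FPKM plus 1 of each member of the mitosis, immediate early, cholesterol and NF-kB lists in the overexpression pairs (OE 1 and OE 2) and the knockdown pairs (KD 1 and KD 2), with a line at the median. Mitotic genes were shifted down in both overexpression pairs (medians -0.15 and -0.24) and cholesterol genes in both knockdown pairs (-0.27 and -0.20).

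The joint comparison tested the difference and the sum of the overexpression and knockdown changes, each of which can be carried by a single comparison. By limma the difference passed for 2 genes with changes of opposite sign, PURPL (adjusted p = 0.0106) and CH17-13I23.3 (adjusted p = 0.0233), the latter at 24 and 12.5 FPKM in OE-PURPL, 7.98 and 11.9 FPKM in ASO-NC, and 0.01 and 0 FPKM in PCDNA and in ASO-PURPL. CDKN2A and CDKN2B did not pass over all genes (0.98 and 0.89, adjusted p = 0.35 for both) and passed when adjusted over the 28 senescence regulators alone (adjusted p = 0.0487). CDKN2A stood at 17.9 and 14.2 FPKM after overexpression against 10.1 and 10.5 FPKM, and at 13.9 and 7.17 FPKM after knockdown against 16.9 and 10.7 FPKM. The sum passed for 2 genes with changes of equal sign, CTB-79E8.3 (adjusted p = 0.018), at 40 and 91.8 FPKM after knockdown against 16.3 and 22.9 FPKM, and IMMP2L (sum of both changes -4.04, SE 0.25, adjusted p = 0.0399). IMMP2L, a subunit of the inner mitochondrial membrane peptidase (chromosome 7, 110663051 to 111562517), stood at 2.87 and 2.48 FPKM after overexpression against 11.5 and 13.4 FPKM, and at 3.91 and 1.74 FPKM after knockdown against 17.5 and 13.7 FPKM. The knockdown change alone passed for none of these 4 genes, and IMMP2L passed in neither comparison (adjusted p = 0.206 and 0.191). With any pair left out, 0 genes passed in either way.

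Across genes, which are not independent replicates, the log2 ratios of the 2 overexpression pairs correlated with a Spearman rho of 0.36 (Pearson r 0.19), and 63.7% of genes had equal signs. For the knockdown pairs rho was 0.08 (r 0.07), with equal signs in 52.7%. Mean overexpression and knockdown changes correlated with a rho of -0.07 (r -0.16). The SD of the log2 ratios was 0.41 and 0.46 in the overexpression pairs and 0.48 and 0.45 in the knockdown pairs.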

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

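Removal of the length and GC trend and the protein-coding test were chosen after seeing the data; the other alternatives were planned, and the tests for count tables did not apply. With 2 pairs per comparison and unknown depth, the count of genes changed by overexpression stayed within 1.5 times its value in 6 of 11 alternatives other than pairs left out. The mitotic, immediate early and cholesterol lists were each called in 16 of 17 alternatives, the exception being fry. The settings behind this and the other tallies are not independent. A comparison fitted alone, or with either pair of the other left out, rests on the same gene statistics. Calls ended in 12 of 17 for NRF2 genes (knockdown), 9 for TGF-beta targets, 7 for the ATF4 list and for interferon-stimulated genes (knockdown), 6 for glycolysis and for secretory factors (knockdown), and 3 to 5 for the other lists (histones 3 of 15). Causes of the changes were not tested, except that leaving out a pair removes a residual degree of freedom and the protein-coding test leaves out PURPL. Among genes past the overexpression test, the call ended in 8 of 13 alternatives for CH17-13I23.3 and RP11-193F5.1, 7 of 13 for CTB-79E8.3 and 6 of 14 for PURPL. All reversals were of genes that did not pass, apart from the ribosomal list.

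Genes changed by overexpression numbered 2 with pseudocount 5, 0 without a filter, 0 in that comparison alone, 1 after the length and GC removal and 0 among protein-coding genes. The latter 2 counts follow from which genes were tested, since CTB-79E8.3, RP11-193F5.1 and CH17-13I23.3 could enter neither test. For knockdown there was 1 with pseudocount 0.1. Genes past the test of the difference (opposite signs) numbered 1 with pseudocount 5, without a trend or with length and GC removed, and 0 without a filter or for protein-coding genes. Genes past that of the sum (equal signs) numbered 1 with pseudocount 0.1, with length and GC removed or for protein-coding genes, and 0 with pseudocount 5, without a filter or without a trend. CH17-13I23.3 (difference) and CTB-79E8.3 (sum) could not enter the length and GC or the protein-coding test, nor PURPL the latter. The lower counts in these settings follow from which genes were tested. Without the replicate block and with quantile normalization, which changed together, there were 5 genes for overexpression, 1 for knockdown, 4 opposite and 0 equal, and 2 lists for each comparison (mitosis and immediate early genes, NF-kB and cholesterol). Estimated correlation left 4 and 1 lists, fry 0 and 0, and eBayes without a trend 4 for knockdown. PURPL after overexpression stayed at 4.87 without a filter and in its comparison alone, where it did not pass (adjusted p = 0.327 and 0.365, in a range from 0.000551 to 0.365 over the alternatives other than pairs left out).

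The Spearman rho of the overexpression pairs was 0.33 and 0.41 with pseudocounts 0.1 and 5, 0.24 without a filter, 0.46 at 5 FPKM, 0.21 with length and GC removed, 0.42 for protein-coding genes and 0.51 for genes above the median level. For knockdown it was 0.06 without a filter, 0.05 at 5 FPKM, 0.10 with length and GC removed, 0.05 for protein-coding genes and 0.02 above the median level.

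Reversed in knockdown were CDKN1A and GAPDH with trimmed-mean scaling (0.03 and 0.04), median centring (0.02 and 0.03) and length and GC removal (0.05 and 0.05), and ACTA2 and ACTB without the replicate block and with quantile normalization (0 and -0.06). Reversed in overexpression by these 2 choices together were GDF15 (-0.06), HMGB1 (-0.10) and IGFBP3 (-0.01), and with length and GC removed GDF15 (-0.13) and ELAVL1 (0.03).

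With pairs left out in turn, none of the 4 genes called after overexpression kept its call. The ranges were 8 to 11 lists for overexpression, 5 to 7 for knockdown and 4.59 to 5.15 for PURPL after overexpression. For overexpression they were -0.09 to 0.36 for GDF15, -0.14 to 0.07 for ACTA2, -0.16 to 0.02 for CCND1, -0.02 to 0.23 for IGFBP3, -0.22 to 0.05 for ELAVL1 and -0.18 to 0.05 for ACTB. For knockdown they were -0.38 to 0.46 for IL6, -0.03 to 0.11 for ELAVL1, -0.13 to 0.17 for ACTB, -0.11 to 0.08 for CDKN1A, -0.04 to 0.16 for MKI67, -0.21 to 0.11 for ACTA2, -0.14 to 0.13 for GAPDH and -0.12 to 0.22 for the ribosomal list.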

Other observations

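All tests in this part, and the genes named for them, were chosen after the results they measure were seen. Lists were also tested for the difference between the overexpression and the knockdown change, and 2 of 9 calls held with an estimated correlation. The 2 were cholesterol biosynthesis (median difference 0.32, adjusted p = 5.14e-05, adjusted p = 1.13e-05 with an estimated correlation) and G2/M and mitosis (-0.23, adjusted p = 2.85e-05, adjusted p = 0.00905 with an estimated correlation). The mitotic list has the limit that its medians in the knockdown arm were 1.74 to 2.09 FPKM, where the pseudocount compresses a change. The arms also differed in their baseline, which cannot be told apart from the perturbations here. MVD, TM7SF2, PMVK and DHCR7 of the cholesterol list differed when adjusted over the list alone (0.89, 0.74, 0.62 and 0.60). For the sum of both changes 6 lists were called, all upward and 0 of them with an estimated correlation (adjusted p from 0.144 to 0.539). They were ribosomal proteins (adjusted p = 4.86e-10), oxidative phosphorylation (2.05e-08), NF-kB targets (median 0.27, 3.87e-06), secretory factors and immediate early genes (0.000467 each) and interferon-stimulated genes (0.0147). In the NF-kB list CXCL1, CXCL2, CXCL8 and PTX3 passed when adjusted over the list alone (0.96, 1.72, 0.96 and 0.85).

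The overexpression ratios followed transcript length and GC content across genes (Spearman -0.34 and -0.36 with length, 0.46 and 0.37 with GC), so short GC-rich transcripts tended to be higher. After this trend was removed, medians were 0.17 for oxidative phosphorylation (SE 0.06, widened here and below for the estimated correlation of members), -0.16 for mitosis (SE 0.05) and 0.13 for immediate early genes (SE 0.04). These lists stayed past the threshold of camera with the preset correlation (adjusted p = 1.03e-08, 2.93e-05 and 0.000275). Ribosomal proteins had a median of 0.12 (SE 0.08). With an estimated correlation the call of immediate early genes was kept (adjusted p = 0.000181, with an estimate of -0.04 taken as 0). Those of oxidative phosphorylation and ribosomal proteins stayed absent (adjusted p = 0.148 and 0.612). That of mitosis, at -0.19 (SE 0.04) before the removal, ended (adjusted p = 0.127) as the estimated correlation of its members went from 0.04 to 0.09. These values argue against the fitted trend as the whole cause for immediate early genes and leave it open for the other lists. The fit used the longest transcript of each gene, and length or GC bias that it missed was not tested. Variation between libraries that moves a list as a block may account for the shifts of 0.24 and 0.18 in oxidative phosphorylation and ribosomal proteins, because the 2 knockdown pairs differed by 0.24 and 0.34 in these lists. That gap was 0.12 against a shift of 0.23 for immediate early genes and 0.01 against -0.19 for mitosis, whose medians in the knockdown arm (1.74 to 2.09 FPKM) lie too near the pseudocount to exclude it, and no biological explanation was tested.

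Interferon-stimulated genes were far higher in the overexpression arm than in the knockdown arm, treated and control libraries alike (IFIT1 at 414 and 438 FPKM in PCDNA against 5.24 and 6.51 FPKM in ASO-NC). Separate normalization of the tables is argued against by the median log2 difference of 3.90 inside the table that holds both arms. Immune cells in the cultures are argued against by 16 of 18 leukocyte markers, which reached at most 3.55 FPKM (LAPTM5) in PCDNA; the other 2, CD68 (315 and 284 FPKM) and LCP1 (8.57 and 8.38 FPKM), were set aside after their values were seen because they reached 77.7 and 65.1 FPKM and 11.7 and 10.1 FPKM in ASO-NC, and CD68 was 4.05-fold and 4.36-fold higher in PCDNA. A response to plasmid delivery may be the cause and cannot be told apart from other differences between the arms, since 0 untreated libraries were among those analysed.

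CH17-13I23.3 was listed at or under 0.01 FPKM in all PCDNA and ASO-PURPL libraries and between 7.98 and 24 FPKM in all OE-PURPL and ASO-NC libraries, thus following PURPL within each arm. Switches between at most 0.01 and at least 10 FPKM were also seen between replicates of the same group, by a mean of 33.2 genes, against a mean of 30.5 between treated and control libraries. Among 123 genes that switched between any 2 libraries, 5 were switched on in both OE-PURPL libraries (CH17-13I23.3, CTB-79E8.3, RP11-193F5.1, RP11-809N8.5 and AC007881.4), where 2.28 would be shared if the pairs were independent. That figure takes all 123 genes as equally prone to switch, which was not tested, so the excess cannot be read as an effect of PURPL. Such estimates thus switched between libraries of the same treatment. Whether they do so inside a table stays open, since the same-group replicates stand in different tables and the treated and control libraries in the same table. Assignment of reads among near-identical copies was not tested.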
